A study of Mus musculus with 8 samples.

How the data were processed

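The series holds 8 RNA sequencing libraries of mouse lung, 4 labelled as wild type with bleomycin (WT_BLM) and 4 labelled as Slc15a3 knockout with bleomycin (KO_BLM). Groups and replicate numbers were taken from the sample titles. Columns named with PHT2, another name of SLC15A3, were matched to the knockout samples by group and replicate number, and 0 columns belonged to other samples. Per the labels' protocols, RNA was extracted with TRIzol, checked by NanoDrop and Bioanalyzer, and made into libraries with a stranded TruSeq mRNA kit, which selects polyadenylated RNA.

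The authors deposited whole-number read counts per gene symbol, 18824 genes each with at least 1 count, which are not normalized. The submitters' processing notes name Trimmomatic, HTSeq, Cufflinks and DESeq, without version or role, and the mm10 build. The aligner, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be shared or lost. The authors also deposited FPKM values. All of these (100% within a relative tolerance of 1e-06) equalled the deposited count divided by the column total and by a single length per gene, so they are no independent measurement and served only for alternatives. Total counts per library were 18878835 to 20180831 in WT_BLM and 17627999 to 18471445 in KO_BLM. Of the gene identifiers in the table, 18715 matched an NCBI gene table of the same assembly (GRCm38), which gave coordinates and neighbours.

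Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total 15), robust glmQLFit and the quasi-likelihood F test between the groups, and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 16.6%. Standard errors of log2 fold changes were taken as the fold change over the square root of F. Levels are CPM, counts scaled to a common library size, with TMM-scaled library sizes. Libraries of each group were compared by chi-square over genes, and no pair agreed within sampling noise (chi-square per degree of freedom 7.48 to 58.1), so all 8 counted as replicates. This check does not show that the libraries came from separate animals. The first principal component of the log2 CPM values held 66.5% of the variance.

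Before the data were examined, 47 gene lists were fixed, covering fibrosis, signalling, metabolism and markers of the cell types that lung can hold. Some genes belong to several lists, so the lists are not independent of each other. Lists with at least 5 tested members (44) were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and given medians with 95% bootstrap intervals (2000 draws). GO and KEGG annotations in the deposited table were tested by one-sided Fisher's exact tests among terms of 10 to 500 tested genes, for higher and lower genes apart. The table does not separate the GO ontologies, so the adjustment ran over all GO terms of a direction and not within each ontology as planned. Single comparisons of list means used two-sided exact permutation tests over the 70 arrangements of 4 against 4, for which 0.0286 is the smallest possible p.

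The rule for named genes was also fixed beforehand. It took the SLC15 family, then, among called genes with a mean of at least 1 CPM in a group, the 12 largest increases and 12 largest decreases, leaving out symbols of predicted genes, pseudogenes and antigen receptor segments, of which 130 were called (92 higher, 38 lower). It then took up to 4 members of smallest p from each list, 18 preset genes, genes of sample state (sex-linked, haemoglobin and clock genes) and the neighbours of Slc15a3 that passed the test. Neighbours aside, this gave 221 tested genes, of which 73 are not reported here. The genes named were picked from among the rule's genes after their values were seen, partly leaving out genes near 0 whose sign moves easily, so stability is also counted over all of the rule's genes. Mfap4, P4ha1, Foxp3, Ctla4 and Tmem132a fall outside the rule and were likewise chosen after their values were seen.

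The alternatives were RLE factors, library totals alone, no filter and a strict filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(FPKM + 1) with and without a filter of 1 FPKM and on log2(FPKM + 0.1), the replicate number as a block, a fit without robust estimation, a fit without the 20 most abundant genes, and each library left out in turn. Removal of each library's trend over gene length or GC content, and term enrichment under other fits, were added after the main results were seen. The steps were tested on simulated data of 14665 genes with the real means and library sizes, of which 198 were changed. At a fold of 1.5, 27.3% of changed genes were recovered, at 2 77.6% and at 4 96.9%, and 2.92% of calls were false. In the real data 41.5% of tested genes were called, a far larger share than was changed in the simulation. These rates therefore need not hold for the real calls. With no list changed, camera called 1 list. The simulated genes varied independently of each other, while estimated correlations within the real lists reached 0.92. The simulation therefore does not show how often camera at its preset correlation calls real lists falsely.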

Results

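Bulk RNA sequencing of mouse lung was used to ask how the loss of Slc15a3 alters gene expression in lungs injured with bleomycin, a DNA-breaking drug that leaves fibrotic scarring in rodent lung. The series concerns this gene in pulmonary fibrosis. SLC15A3 is a proton-coupled transporter of histidine and small peptides in the endolysosomal membrane. The 8 libraries comprised 4 from wild-type mice (WT_BLM) and 4 from Slc15a3 knockout mice (KO_BLM). The mice, 8 weeks of age, received 2 mg/kg bleomycin in 50 µl of saline through the trachea on day 0 and were killed on day 21. Saline-treated mice were not analysed here, so every difference is one between the WT_BLM and KO_BLM libraries after bleomycin. The sample labels used here give no batch, hour of killing or handling. A difference in these between the groups could not be told apart from the genotype. Total counts per library ran from 18878835 to 20180831 in WT_BLM and from 17627999 to 18471445 in KO_BLM. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

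Slc15a3 transcripts were nearly lost in the knockout libraries. The gene, NCBI Gene 65221, lies on chromosome 19 from 10842544 to 10857915 in the mm10 assembly. Its counts were 935, 1124, 974 and 841 in WT_BLM replicates 1 to 4, and 8, 5, 18 and 15 in KO_BLM replicates 1 to 4. Exact Poisson 95% intervals ran from 785 to 900 for the lowest wild-type count and from 10.7 to 28.4 for the highest knockout count. These intervals cover counting error only. As CPM (counts scaled to library size), the level was 51.3 ± 4.11 CPM (SD, n = 4) in WT_BLM and 0.610 ± 0.303 CPM (SD, n = 4) in KO_BLM. By pooled scaled counts 1.20% was left, and the fitted reduction was 82.3-fold (log2 fold change −6.36, SE 0.23, edgeR adjusted p = 9.36e-07). The tested relatives of the same transporter family did not pass the test. Slc15a1 had a log2 fold change of −0.33 (SE 0.30, edgeR adjusted p = 0.401), Slc15a2 of 0.37 (SE 0.25, adjusted p = 0.255) and Slc15a4 of 0.15 (SE 0.08, adjusted p = 0.165). Slc15a2 was called without WT_BLM replicate 4 (log2 fold change 0.71, edgeR adjusted p = 0.0044, range 0.0044 to 0.492 across alternatives) and by limma-voom (adjusted p = 0.0177), and Slc15a4 with library totals alone (adjusted p = 0.0418, range 0.0418 to 0.370). Slc15a5 had 2 counts in all WT_BLM libraries and 3 in all KO_BLM libraries and was not tested. Of the genes near Slc15a3, Tmem109 rose (log2 fold change 0.52, SE 0.12, edgeR adjusted p = 0.00802) and so did Cd5, a T cell surface receptor (1.45, SE 0.37, adjusted p = 0.0121). The gene between Cd5 and Slc15a3, a T cell marker like Cd5, was not called (1.01, SE 0.38, edgeR adjusted p = 0.0572). As 41.5% of all tested genes were called, these rises do not show a local effect of the knockout. Tmem132a, whose annotated span overlaps the end of Slc15a3, had a log2 fold change of −0.05 (SE 0.17, edgeR adjusted p = 0.831), and its sign changed without WT_BLM replicate 2 (0.10) or 3 (0.0075), with library totals alone (0.03) and in limma on FPKM.

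Of 14746 genes tested, 3057 were higher and 3061 lower in KO_BLM, together 41.5%, and 1783 of them had an absolute log2 fold change of at least 1. The values of the groups did not overlap for 6036 genes, 40.9% of those tested, where chance gives 2.86% for 4 against 4. Scaling by library totals alone in place of TMM factors gave 3789 higher and 2253 lower, which moved the share of higher calls from 50.0% to 62.7%. Among the genes with the largest increases, Slc7a10, an amino acid transporter, went from 1.22 ± 0.256 to 45.1 ± 15.3 CPM (SD, n = 4), a 36.7-fold rise. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 21.4-fold, from 6.55 ± 1.21 to 140 ± 72.4 CPM. Car3, Slc5a12, Colq, Cst8, Mesp1 and Bcan rose between 11.1-fold and 31.3-fold, and so did the lymphocyte genes Gzma, Klre1, Klra7 and S1pr5, by 10.9-fold to 12.8-fold. Some of these folds rest on 1 library: without WT_BLM replicate 2, Klra7 was 26.7-fold, Klre1 20.4-fold and Gzma 18.5-fold higher, without WT_BLM replicate 3 Slc5a12 36.6-fold in place of 15.4-fold, without KO_BLM replicate 1 Cst8 7.66-fold in place of 12.3-fold, and without KO_BLM replicate 4 Car3 12.5-fold in place of 31.3-fold. Car3 was uneven, at 4.34 ± 5.36 CPM in KO_BLM, and was not called by limma on unfiltered log2(FPKM + 1) values (adjusted p = 0.0679, range 1.84e-07 to 0.0679 across alternatives). Klra7 has close paralogs with which reads can be shared, so its level is uncertain.

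The largest decreases included secreted and matrix genes. Gpr37 fell 65.0-fold, Col11a1 41.2-fold, Hmga2 40.2-fold, Tnfsf18 35.8-fold, Mmp10 34.7-fold, the BMP antagonist Grem1 28.6-fold and Lrrc15, a marker of activated fibroblasts, 26.8-fold. Without KO_BLM replicate 3 the fall of Mmp10 was 64.8-fold. Of these, Tnfsf18 went from 9.37 ± 1.66 to 0.253 ± 0.0837 CPM (SD, n = 4; log2 fold change −5.16, SE 0.27, edgeR adjusted p = 2.54e-06) and Grem1 from 8.61 ± 1.72 to 0.293 ± 0.118 CPM. For 4 further genes the knockout level rests on very few counts. Dmp1 had 167 counts over the WT_BLM libraries and 1 over the KO_BLM libraries, a scaled ratio of 165 with an exact counting interval of 29.2 to 6550. Dspp had 210 and 3 counts (ratio 69.1, interval 23.3 to 338), Gbx2 169 and 3 (55.6, 18.7 to 272) and Adamts16 83 and 2 (41.0, 11.0 to 344). Without KO_BLM replicate 3, Dspp had 1 knockout count (ratio 154, interval 27.3 to 6110). The knockout counts of Dmp1 and Adamts16 came from KO_BLM replicate 4 alone, and without it they were at least 40.8-fold and 20.3-fold lower, against a floor of 3 counts over the group.

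Extracellular matrix genes were lower in KO_BLM. Of 40 tested genes for fibrillar collagens and other matrix proteins, 34 fell, 2 rose (Mfap4 and P4ha1) and 4 were not called. Adjusted over the list alone, the numbers were also 34 and 2. The median log2 fold change was −1.75. Col1a1, a chain of type I collagen, went from 2427 ± 291 to 441 ± 25.8 CPM (SD, n = 4), 5.51-fold lower (log2 fold change −2.46, SE 0.11, edgeR adjusted p = 1.35e-06). Col1a2 fell 4.41-fold, Col3a1 2.24-fold, Col5a1 5.20-fold, the fibulin Fbln2 8.29-fold and the collagen prolyl hydroxylase subunit P4ha3 8.30-fold. Fibronectin, Fn1, fell 6.21-fold, from 5230 ± 643 to 843 ± 315 CPM. Spp1, osteopontin, fell with an edgeR adjusted p of 0.0306 (log2 fold change −2.32, SE 0.74), at 120, 182, 1562 and 1703 CPM in KO_BLM replicates 1 to 4 against 4105 to 4744 CPM in WT_BLM. Its call was lost without WT_BLM replicate 1 (adjusted p = 0.0554), 2 (0.0756), 3 (0.0550) or 4 (0.0876), without KO_BLM replicate 2 (0.0553) and with no filter on low counts (0.0846), over a range of 0.00135 to 0.0876 across alternatives. The matrix list passed camera's test (adjusted p = 7.45e-44) and was the only list of the 44 tested that also passed with an estimated correlation (adjusted p = 0.00862).

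**Figure D1:**
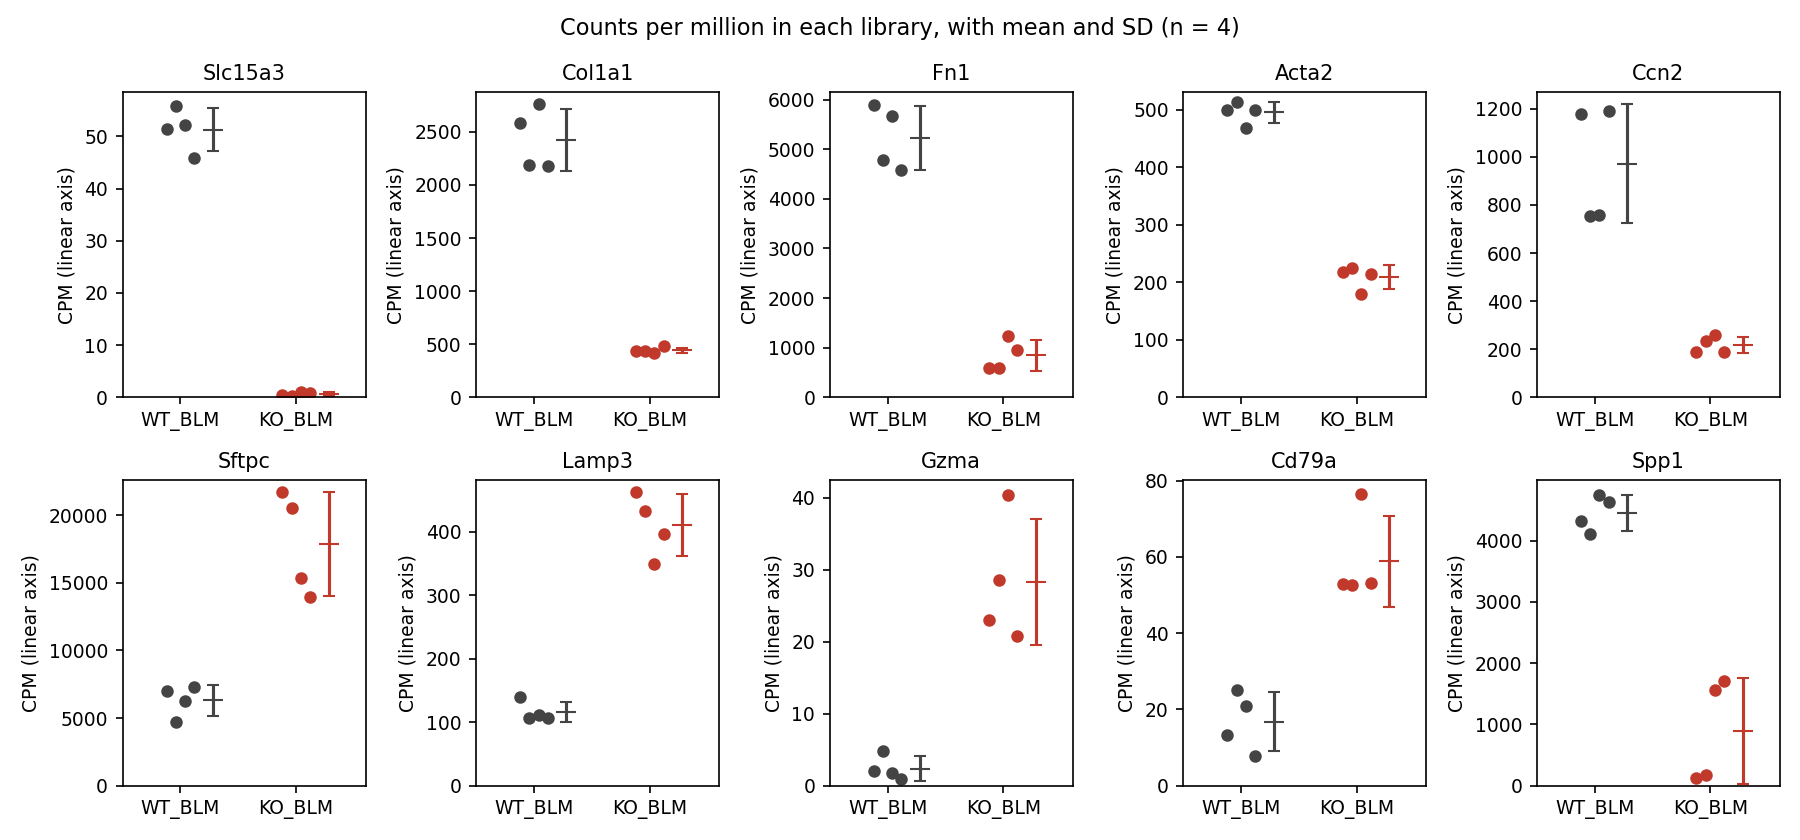
CPM (read counts scaled to library size, linear axes from 0) of 10 genes in each of the 4 WT_BLM and 4 KO_BLM libraries, points for libraries and bars for the mean and SD. Slc15a3, Col1a1, Fn1, Acta2 and Ccn2 lay lower in all KO_BLM libraries, Sftpc, Lamp3, Gzma and Cd79a lay higher, and Spp1 ran from 120 to 1703 CPM within KO_BLM.

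Contractile, TGF-beta and matrix protease genes were lower as well. Of 14 contractile genes of myofibroblasts and smooth muscle, 8 fell and 1 rose (9 and 2 adjusted over the list alone) (camera adjusted p = 0.000194; adjusted p = 0.421 with an estimated correlation). Acta2, smooth muscle actin, was 2.37-fold lower, Tagln 2.37-fold and Cald1 1.90-fold. Acta2 went from 495 ± 18.8 to 209 ± 20.4 CPM (SD, n = 4). In the TGF-beta pathway, 13 of 21 genes fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 6.72e-07; adjusted p = 0.0794 with an estimated correlation). Ccn2 was 4.47-fold lower, Ltbp2 4.03-fold and the ligand gene Tgfb1 1.44-fold. Of 18 metalloproteinases and inhibitors, 12 fell and 0 rose, the same 12 and 0 adjusted over the list alone, including Mmp14 at 3.49-fold and Adamts12 at 8.63-fold lower (camera adjusted p = 4.21e-11; adjusted p = 0.0794 with an estimated correlation).

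Camera's preset correlation called 23 lists, 10 higher and 13 lower. Among the 35 ways of splitting the 8 libraries into 4 and 4, 14 gave at least 23 lists, and splits other than the real one gave up to 30. Of these 14, 12 keep 3 libraries of each genotype together and so carry part of the genotype difference. The 18 splits that divide each genotype evenly gave 7 to 23 lists, 1 of them as many as the real one.

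**Figure D2:**
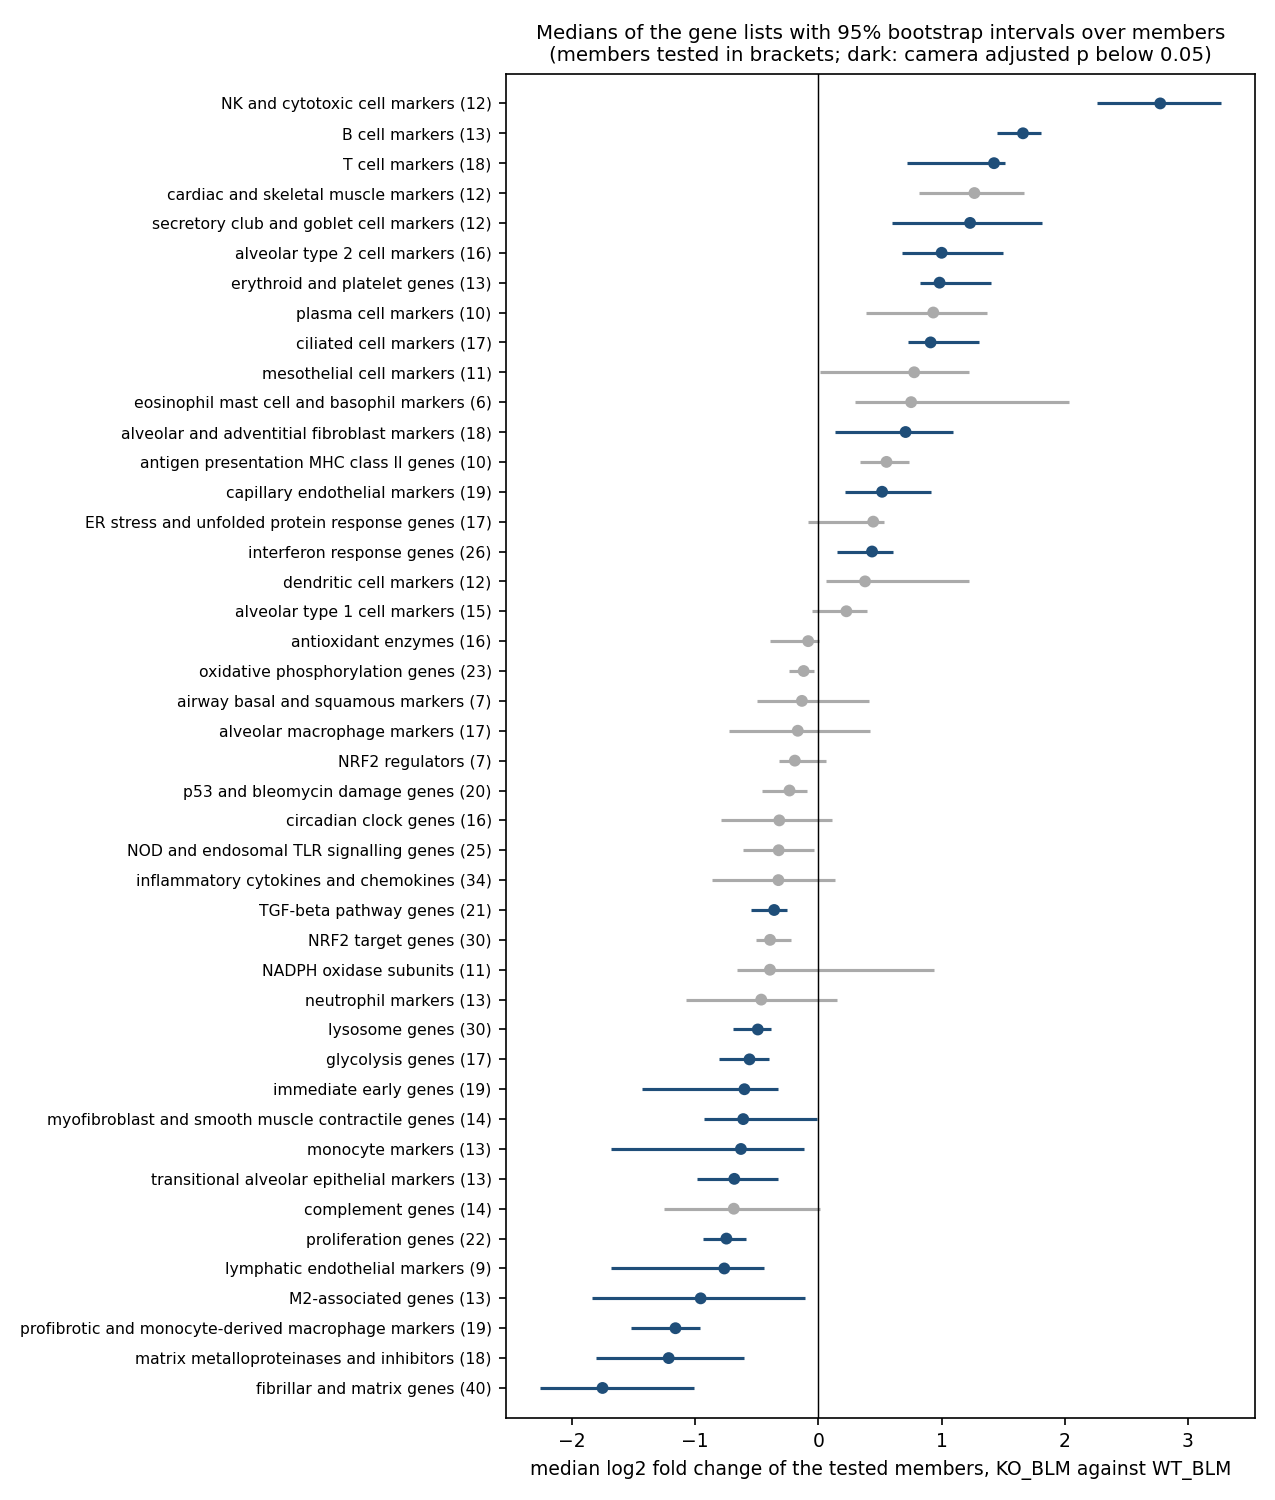
Median log2 fold change of the tested members of each of 44 gene lists (x axis, KO_BLM against WT_BLM; number tested in brackets), with 95% bootstrap intervals over members as lines and camera calls in dark blue. The matrix list had the lowest median, −1.75, and the natural killer list the highest, 2.77.

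Markers of recruited macrophages and alternatively activated macrophages were lower in KO_BLM. Of 19 markers of profibrotic and monocyte-derived macrophages, 12 fell and 1 rose, likewise 12 and 1 adjusted over the list alone (camera adjusted p = 0.000227; adjusted p = 0.460 with an estimated correlation). C1qa was 2.87-fold and Arg1, arginase, 13.3-fold lower. Arg1 went from 55.5 ± 25.3 to 4.13 ± 2.98 CPM (SD, n = 4). In KO_BLM, replicates 1 and 2 lay below 3 and 4, with Arg1 at 1.54, 1.56, 6.46 and 6.94 CPM and C1qa at 81.3, 123, 219 and 169 CPM in replicates 1 to 4. Of 13 genes associated with the M2 state, 9 fell and 0 rose, 9 and 0 adjusted over the list alone, with the mannose receptor Mrc1 2.76-fold lower (camera adjusted p = 0.000532; adjusted p = 0.0888 with an estimated correlation). Monocyte markers had 8 of 13 lower, such as F13a1 at 4.65-fold, and 2 higher, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00487; adjusted p = 0.383 with an estimated correlation). Of 30 lysosome genes 17 fell and 0 rose, 18 and 1 adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.564 with an estimated correlation). Without KO_BLM replicate 1 or 2, 10 lysosome genes were called lower. Grn was 1.81-fold, Cd63 1.95-fold and the cathepsin Ctsh 2.49-fold lower. Some of these lists share genes with each other and with the matrix list, so their falls are not independent. Fn1 was in the matrix, M2 and monocyte lists, and Spp1 in the matrix and profibrotic macrophage lists. Arg1 was in the profibrotic macrophage and M2 lists, and Cd63 in the profibrotic macrophage and lysosome lists.

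Other myeloid lists did not pass camera's test. Complement genes had 5 of 14 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0521), with C1qc 3.19-fold lower. Alveolar macrophage markers went both ways, with 4 of 17 higher and 5 lower, also 4 and 5 adjusted over the list alone, Cidec 4.40-fold up and Slc7a2 3.30-fold down (camera adjusted p = 0.466); 3 were lower without WT_BLM replicate 4 or KO_BLM replicate 2. Neutrophil markers had 4 of 13 lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.0692), including Trem1 at 3.64-fold and Il1r2 at 5.03-fold. Dendritic cell markers had 3 of 12 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.246), with Clec9a, a marker of cross-presenting dendritic cells, 3.81-fold higher and Fscn1 2.37-fold lower. Without WT_BLM replicate 2, 7 dendritic cell markers were higher. Of 6 eosinophil, mast cell and basophil markers 3 rose, 4 adjusted over the list alone, with the mast cell chymase Cma1 6.97-fold and Kit 1.53-fold higher (camera adjusted p = 0.0553). Class II antigen presentation genes had 1 of 10 higher, likewise 1 adjusted over the list alone, which was H2-Ob at 3.59-fold (camera adjusted p = 0.0830), and 8 of 10 without WT_BLM replicate 2.

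Markers of surfactant-producing type 2 alveolar cells were higher in KO_BLM. Of 16 markers, 14 rose and 0 fell, likewise 14 and 0 adjusted over the list alone (camera adjusted p = 3.50e-16; adjusted p = 0.0888 with an estimated correlation). Sftpc, surfactant protein C, went from 6311 ± 1148 to 17874 ± 3821 CPM (SD, n = 4), 2.83-fold higher (log2 fold change 1.5, SE 0.19, edgeR adjusted p = 0.000343). Sftpa1 rose 3.85-fold, Lamp3 3.52-fold, Hc 6.28-fold and Lyz1 9.04-fold. Reads of Lyz1 can be shared with its near copy Lyz2. Markers of a transitional alveolar state moved the opposite way, with 9 of 13 lower and 0 higher (10 and 0 adjusted over the list alone) (camera adjusted p = 0.000140; adjusted p = 0.421 with an estimated correlation). Cldn4 was 5.79-fold, Sfn 2.63-fold and Plaur 2.23-fold lower. Type 1 alveolar markers had 5 of 15 higher and 1 lower, as when adjusted over the list alone, with Rtkn2 2.41-fold and Cav1 1.67-fold higher and Krt7 1.74-fold lower (camera adjusted p = 0.114), and 3 were higher without WT_BLM replicate 2 or 3 or KO_BLM replicate 2, 3 or 4. Ager, an abundant type 1 cell gene, was at 2504 ± 402 and 2559 ± 148 CPM (SD, n = 4; log2 fold change 0.03, SE 0.12, edgeR adjusted p = 0.855), and its sign changed without WT_BLM replicate 2 (−0.04) or 3 (−0.02) or KO_BLM replicate 3 (−0.0084).

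Airway epithelial markers were higher too. Of 17 markers of ciliated cells, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with Tppp3 3.88-fold and Ccdc39 2.61-fold higher (camera adjusted p = 4.53e-07; adjusted p = 0.421 with an estimated correlation). Of 12 markers of club and goblet cells 6 rose and 0 fell (7 and 0 adjusted over the list alone), including Cyp2f2 at 4.58-fold and Scgb3a2 at 2.55-fold (camera adjusted p = 0.0211; adjusted p = 0.431 with an estimated correlation). The club and goblet list was not called without KO_BLM replicate 4 (camera adjusted p = 0.0603). Airway basal and squamous markers had 1 of 7 higher, likewise 1 adjusted over the list alone, which was Dapl1 at 4.51-fold. The median and mean of that list lay below 0, at −0.13 each, while camera's direction was upward (adjusted p = 0.791) and turned without WT_BLM replicate 3 or 4, without KO_BLM replicate 4 and without the filter on low counts.

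Lymphocyte markers were higher in KO_BLM. All 12 markers of natural killer and cytotoxic cells rose, and all 12 adjusted over the list alone (camera adjusted p = 4.25e-12; adjusted p = 0.233 with an estimated correlation). The median log2 fold change was 2.77, with the perforin gene Prf1 7.49-fold, Gzmb 6.17-fold and Gzma 11.9-fold higher. Gzma went from 2.34 ± 1.71 to 28.2 ± 8.74 CPM (SD, n = 4). Of 13 B cell markers 12 rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 1.01e-05; adjusted p = 0.421 with an estimated correlation). The B cell receptor components Cd79a and Cd79b were 3.49-fold and 3.35-fold higher. Of 18 T cell markers 11 rose and 2 fell (13 and 2 adjusted over the list alone) (camera adjusted p = 0.000389; adjusted p = 0.647 with an estimated correlation). Cd8a was 3.55-fold, Cd28 2.78-fold and Cd2 2.70-fold higher, and the regulatory T cell genes Foxp3 (log2 fold change −0.85, edgeR adjusted p = 0.0418) and Ctla4 (−0.99, adjusted p = 0.0277) were lower. The call of Foxp3 was lost under 9 alternatives, including 5 left-out libraries and library totals alone (adjusted p from 0.016 to 0.112 across alternatives), and that of Ctla4 without WT_BLM replicate 1 (0.0539), 2 (0.0514) or 3 (0.0529) or KO_BLM replicate 2 (0.0797). Plasma cell markers had 2 of 10 higher, among them Prdm1 at 2.06-fold, and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0893), with 6 higher without WT_BLM replicate 3, 5 without KO_BLM replicate 1 and 1 without WT_BLM replicate 1 or 4 or KO_BLM replicate 3 or 4. Red cell and platelet genes rose beside these lists, with 8 of 13 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.421 with an estimated correlation). The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, whose near-identical copies can share reads, rose 1.83-fold to 2.69-fold and the platelet gene Ppbp 4.93-fold. The mean log2 CPM of the haemoglobin genes was 1.11 higher in KO_BLM (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows).

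**Figure D3:**
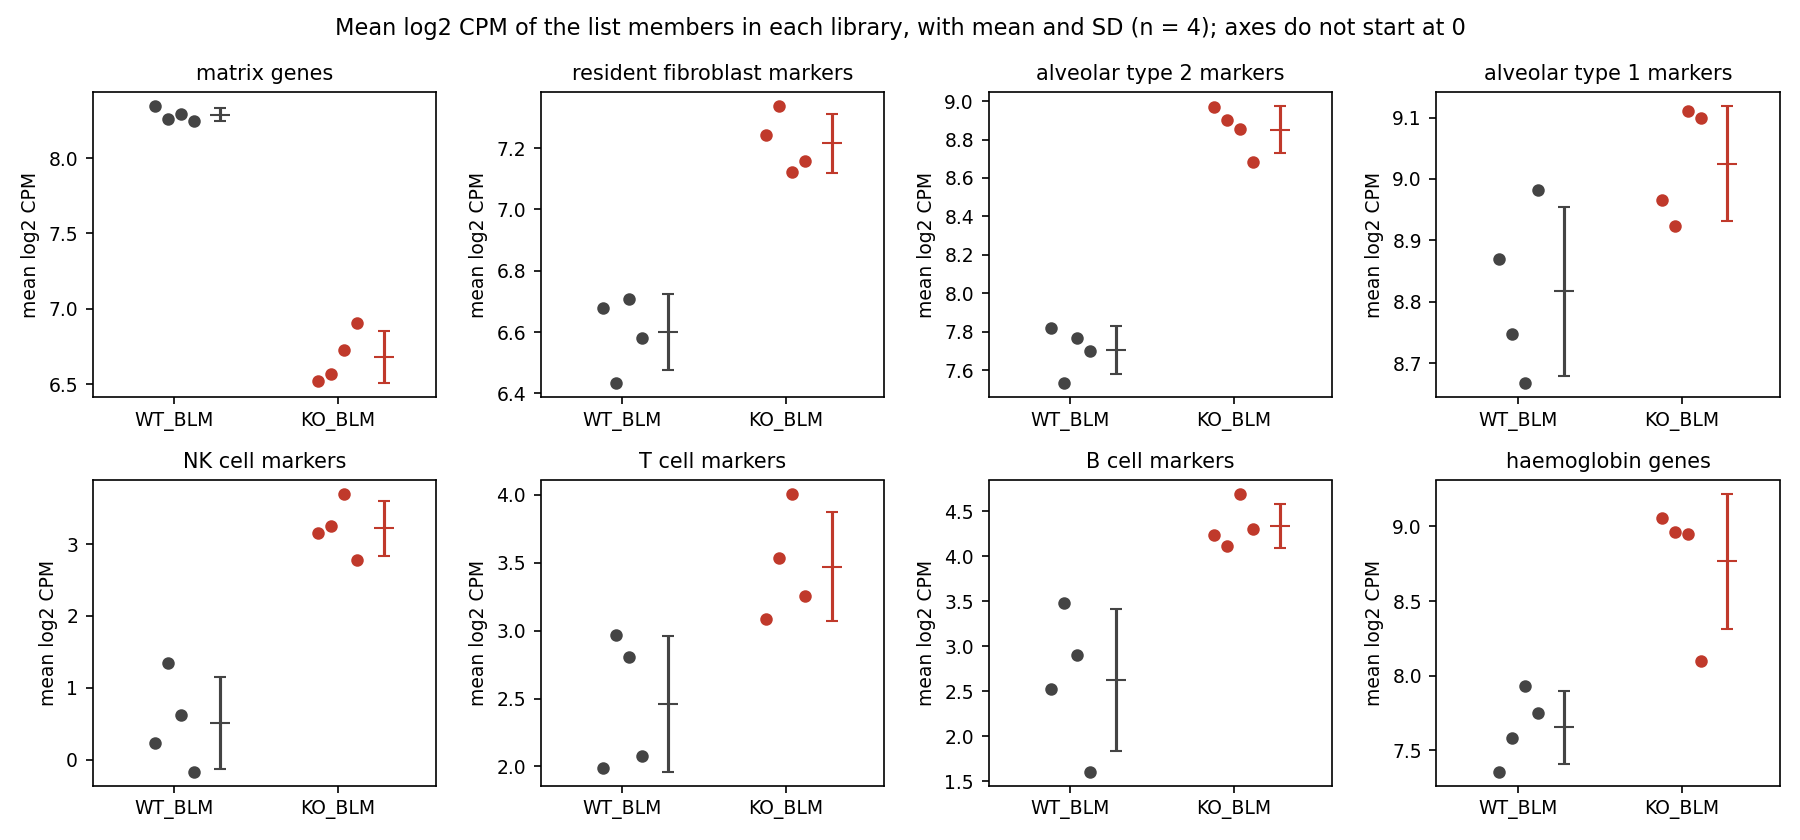
Mean log2 CPM over the tested members of 7 gene lists and the 4 haemoglobin genes in each library, with points for libraries and bars for the mean and SD (4 libraries per group; axes do not start at 0). Matrix genes lay lower in all KO_BLM libraries (difference −1.61), resident fibroblast markers higher (0.615), and natural killer, T and B cell markers higher by 2.71, 1.01 and 1.71.

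Resident fibroblast and capillary markers were higher while lymphatic markers were lower. Of 18 markers of alveolar and adventitial fibroblasts 12 rose and 2 fell, 12 and 2 adjusted over the list alone (camera adjusted p = 0.000240; adjusted p = 0.233 with an estimated correlation). The transcription factor gene Tcf21 was 3.22-fold, Inmt 4.52-fold and Dpep1 4.20-fold higher. Of 19 capillary endothelial markers 12 rose and 2 fell, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.651 with an estimated correlation). Hpgd was 3.01-fold and the VEGF receptor gene Kdr 1.89-fold higher, and Vwf 1.86-fold lower. The capillary list did not pass fry's directional test (adjusted p = 0.0619). Lymphatic endothelial markers had 6 of 9 lower and 0 higher (7 and 0 adjusted over the list alone), with Reln 3.22-fold and Flt4 1.70-fold lower (camera adjusted p = 0.00284; adjusted p = 0.208 with an estimated correlation). Mesothelial markers had 4 of 11 higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.159), with Rspo1 2.33-fold higher and Msln 1.97-fold lower, and 7 higher without WT_BLM replicate 2. Heart and skeletal muscle markers had 5 of 12 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0794), with the cardiac actin Actc1 3.21-fold higher. Without WT_BLM replicate 3 or KO_BLM replicate 4, 3 muscle markers were higher, and 2 without WT_BLM replicate 4 or KO_BLM replicate 3. Myoglobin, Mb, passed the test (log2 fold change 3.0, SE 0.90, edgeR adjusted p = 0.0234; 8.01-fold, and 4.57-fold without KO_BLM replicate 4) but had 0.881, 1.90, 10.9 and 18.3 CPM in KO_BLM replicates 1 to 4. Its call was lost without WT_BLM replicate 3 (adjusted p = 0.0559) or 4 (0.0526) or KO_BLM replicate 3 (0.0512) or 4 (0.0688), with the replicate block (0.0541), by limma-voom (0.177) and in limma on log2(FPKM + 1), filtered (0.0729) or not (0.113), and on log2(FPKM + 0.1) (0.0653), over a range of 0.00797 to 0.177 across alternatives. Of 4 tested adipocyte and thymus markers, too few for a list test, 2 rose, Cidec and Cd1d1, and 2 were also called adjusted over the list alone. The rise of Cd1d1 was small (log2 fold change 0.39, SE 0.14, edgeR adjusted p = 0.0456), and its call was lost with no filter on low counts (adjusted p = 0.0555), with the replicate block (0.0757) and without replicate 1, 2 or 3 of either group (0.0601 to 0.119).

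Glycolysis genes were lower in KO_BLM, while NRF2 targets, NRF2 being the main transcription factor of the oxidative stress response, went both ways. Of 17 glycolysis genes 14 fell and 0 rose, 14 and 0 adjusted over the list alone (camera adjusted p = 1.58e-06; adjusted p = 0.233 with an estimated correlation). The glucose transporter gene Slc2a1 was 2.17-fold, Pkm 2.04-fold and Eno1 2.52-fold lower. Of 30 NRF2 targets 12 fell and 5 rose (15 and 7 adjusted over the list alone; camera adjusted p = 0.0915), with the haem oxygenase gene Hmox1 2.42-fold, Srxn1 1.90-fold and Abcc1 1.54-fold lower and Gstm1, which has close paralogs, 2.61-fold higher. Nqo1 had a log2 fold change of −0.60 (SE 0.27, edgeR adjusted p = 0.102). Of 7 NRF2 regulators 2 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.486), with Bach1, a repressor of NRF2 targets, 1.32-fold lower. The other of the 2 had an adjusted p of 0.0487 and lost its call under 16 alternatives, 7 of them left-out libraries. Nfe2l2, which encodes NRF2, had a log2 fold change of 0.37 (SE 0.15, edgeR adjusted p = 0.0782) and Sqstm1 of −0.26 (SE 0.11, adjusted p = 0.0703), which was called without KO_BLM replicate 3 (adjusted p = 0.0495), by DESeq2 (0.0409) and by limma-voom (0.0346, range 0.0346 to 0.175 across alternatives).

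Oxidase and antioxidant genes moved in both directions, as did called genes at large, which made up 41.5% of all genes tested. Of 11 NADPH oxidase subunits 3 rose and 3 fell, also when adjusted over the list alone, with Nox1 7.76-fold and Noxa1 5.76-fold higher from low levels and the phagocyte subunit Ncf1 1.74-fold lower (camera adjusted p = 0.874, downward, with a median log2 fold change of −0.39 and a mean of 0.22). Cybb, the catalytic phagocyte subunit, had a log2 fold change of −0.51 (SE 0.31, edgeR adjusted p = 0.201) and was called by limma-voom (adjusted p = 0.00994, range 0.00994 to 0.413 across alternatives). Of 16 antioxidant enzymes 3 rose and 5 fell, likewise adjusted over the list alone (camera adjusted p = 0.576), with catalase, Cat, 2.05-fold and Sod3 1.63-fold higher and Gpx3 1.78-fold lower; the median of this list, −0.08, turned to 0.00555 with library totals alone, and 3 fell without KO_BLM replicate 2. Of 23 oxidative phosphorylation genes 8 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.211), the riser being Ndufb3 at 1.38-fold. The fallers depended on the libraries: 0 were called without KO_BLM replicate 2, 2 without WT_BLM replicate 1, 4 without KO_BLM replicate 1 or 4 and 5 without WT_BLM replicate 2 or 4. Cox5a fell 1.28-fold (edgeR adjusted p = 0.0145), a call lost without KO_BLM replicate 2 (adjusted p = 0.0524), with library totals alone (0.0596) and in limma on log2(FPKM + 1), filtered (0.0548) or not (0.0658), and on log2(FPKM + 0.1) (0.0557), over a range of 0.00244 to 0.0658 across alternatives.

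Inflammatory signalling genes also went in both directions, like called genes at large. Of 34 cytokines and chemokines 11 fell and 5 rose, as when adjusted over the list alone (camera adjusted p = 0.0893), with the monocyte attractant Ccl2 10.6-fold, Cxcl13 3.46-fold, Cxcl14 2.71-fold and Il6 6.56-fold lower. Without KO_BLM replicate 4 the fall of Ccl2 was 16.5-fold. Il1b had a log2 fold change of −0.31 (SE 0.39, edgeR adjusted p = 0.552) and Tnf of −0.08 (SE 0.25, adjusted p = 0.809), and the sign for Tnf changed with library totals alone (0.0031) and without KO_BLM replicate 1 (0.07). Of 25 genes of NOD and endosomal Toll-like receptor signalling 7 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 0.0915), with Tlr13 2.66-fold and Relb 1.57-fold lower and Tlr3 1.34-fold higher. Of 26 interferon response genes 9 rose and 2 fell, 9 and 2 adjusted over the list alone, with Gbp7 1.81-fold and Isg20 1.94-fold higher (camera adjusted p = 0.0271; adjusted p = 0.651 with an estimated correlation). Without WT_BLM replicate 1, 5 interferon response genes were higher, and 14 without WT_BLM replicate 2. The interferon list was not called without WT_BLM replicate 1 (adjusted p = 0.0902) or 4 (0.0705) or KO_BLM replicate 4 (0.103), nor by fry (adjusted p = 0.116).

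Cell cycle and immediate early genes were lower in KO_BLM. Of 22 proliferation genes 12 fell and 0 rose (13 and 0 adjusted over the list alone) (camera adjusted p = 0.00129; adjusted p = 0.651 with an estimated correlation; fry adjusted p = 0.0761). The cyclin genes Ccnb1 and Ccnb2 were 2.34-fold and 2.06-fold and Birc5 2.25-fold lower. Without WT_BLM replicate 4, 20 of the 22 were lower. Of 19 immediate early genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with Ccn1 2.96-fold, Egr3 3.29-fold and Fosl2 2.37-fold lower (camera adjusted p = 0.000106; adjusted p = 0.313 with an estimated correlation). Of 20 p53 and damage genes 7 fell and 1 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0880), with the senescence gene Cdkn2a 4.17-fold and Cdkn1a 1.37-fold lower and Bbc3 1.41-fold higher. Of 17 genes of the unfolded protein response 6 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.141), with Creld2 1.85-fold higher, and 10 rose without KO_BLM replicate 3. Of 16 clock genes 6 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 0.278), with Per2 2.37-fold lower and Npas2 4.14-fold higher. Camera looks for a shift in a single direction, so it can miss clock genes that move both ways. No cause of their shifts was tested, and a different hour of killing in the 2 groups could not be told apart from the genotype. None of 4 tested sex-linked genes was called by edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p below 0.05: Ddx3y had a log2 fold change of −0.09 (SE 0.12, adjusted p = 0.579), whose sign changed with library totals alone (0.0032) and in limma on FPKM, and Kdm5d of 0.22 (SE 0.11, adjusted p = 0.135).

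Annotation terms carried in the deposited table were tested as well. Among the genes higher in KO_BLM, 131 of 302 tested cilium genes were called where 61.5 would be drawn by chance (one-sided Fisher's exact test, adjusted p = 1.73e-16), and 25 of 42 genes of xenobiotic metabolism by cytochrome P450 (7.97 by chance, adjusted p = 2.10e-06). Among the genes lower in KO_BLM, 120 of 228 extracellular matrix genes were called (48.5 by chance, adjusted p = 3.46e-22), 54 of 103 basement membrane genes (21.9 by chance, adjusted p = 2.22e-09), 61 of 130 ribosome genes (31.1 by chance, adjusted p = 1.02e-06), 25 of 44 proteasome genes (10.5 by chance, adjusted p = 0.000176) and 48 of 121 lysosome genes (29.0 by chance, adjusted p = 0.00269). The ribosome genes shifted little, at a median log2 fold change of −0.24. In all, 177 terms passed, and since terms share genes and genes are not independent, they serve as a ranking.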

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

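In 334 groups of 4 values (the genes named in the text and the list means, in each genotype), the highest or lowest library was checked for standing apart from the other 3 by Dixon's test at its 95% critical value. It stood apart in 18 groups, where chance gives about 1 in 20, or 16.7. KO_BLM replicate 4 accounted for 6 and WT_BLM replicate 4 for 5. This test cannot show 2 libraries standing apart from 2. In KO_BLM, replicates 1 and 2 differed by a chi-square per degree of freedom of 7.48 and replicates 3 and 4 by 19.04, against 27.8 to 50.1 between these pairs. No explanation was tested for these values.

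In WT_BLM, replicate 4 was above the others for Bach1 (94.3 CPM against 71.7 to 74.0), Ndufb3 (32.4 against 28.1 to 28.7), Cox5a (101 against 89.4 to 90.3) and Fosl2 (263.8 against 163.4 to 165.5), and below them for the platelet gene Ppbp (1.42 against 4.07 to 4.36). WT_BLM replicate 2 was above the others for the natural killer genes Klra7 (0.397 CPM against 0.0545 to 0.107) and Klre1 (0.744 against 0.110 to 0.218). Lamp3 was higher in WT_BLM replicate 1 (139.9 CPM against 106.9 to 111.7).

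In KO_BLM, replicate 4 was above the others for Ccl2 (5.84 CPM against 1.56 to 2.29) and Ccn1 (187.7 against 109.1 to 122.3), and below them for Kit (199.9 against 228.6 to 232.1) and for the mean log2 CPM of the haemoglobin genes (8.10 against 8.95 to 9.06). It alone held counts of Dmp1 (0.0521 CPM) and Adamts16 (0.104 CPM), both at 0 in the other 3 libraries. KO_BLM replicate 3 was above the others for the B cell genes H2-Ob (55.2 CPM against 35.0 to 36.2) and Cd79a (76.6 against 52.5 to 53.2). KO_BLM replicate 1 was above them for Plaur (61.7 CPM against 51.9 to 53.5) and had 0 CPM of Gbx2, against 0.0521 to 0.0558.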

How the results depend on the processing

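The trends over gene length and GC content and the term counts under other fits were added after the main results were seen. The numbers of higher genes (main 3057) and lower genes (3061) stayed within 1.5 times except that limma on log2(FPKM + 1) gave 2005 lower genes and on log2(FPKM + 0.1) 1998. The number with an absolute log2 fold change of at least 1 (1783) was 1064 with the strict filter, which tests fewer genes. It was 794 on log2(FPKM + 1) and 799 on the same scale unfiltered. That pseudocount shrinks low genes, but on log2(FPKM + 0.1) the number was still 1244. The limma fits also differ from the main fit in test and scaling, and these parts were not separated. Leaving out 1 library gave 2316 to 2957 higher, 2178 to 2896 lower and 1636 to 1920 past 1. No called gene was called in the other direction under any of these settings. Slc15a3 stayed called throughout, at −6.93 to −4.13. With an estimated correlation 1 list remained of 23; leaving out 1 library gave 23 to 28. The annotation term enrichment (177 terms) gave 162 to 216 under the other fits run.

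Of 221 tested genes that the naming rule picked (neighbours of Slc15a3 aside), 196 were called, and 181 of these were called under every alternative set beforehand that tests them. The other 15 lost the call at least once, and 0 of the 196 changed sign. The selection matters here: 10 of the 60 called genes that the text leaves out lost the call, against 5 of the 136 called genes it names (Car3, Spp1, Cox5a, Mb and Cd1d1). Foxp3 and Ctla4, named outside the rule, lost it too. Among 25 uncalled rule genes, 11 gained a call and 6 changed sign. Of these 6 the text names 3: Tnf, 0.0031 with library totals alone and 0.073 without KO_BLM replicate 1 (range −0.32 to 0.073 over left-out libraries); Ddx3y, 0.0032 with library totals alone, 0.012 on log2(FPKM + 1), filtered or not, and 0.014 on log2(FPKM + 0.1); and Ager, −0.041 to 0.13 over left-out libraries. Tmem132a, outside the rule and never called, changed sign as well: 0.029 with library totals alone, 0.059 on log2(FPKM + 1), filtered or not, 0.069 on log2(FPKM + 0.1), and −0.186 to 0.097 over left-out libraries. The airway basal list, never called, turned direction without the filter on low counts (adjusted p = 0.551) and without WT_BLM replicate 3 (0.863) or 4 (0.837) or KO_BLM replicate 4 (0.886), its adjusted p running from 0.397 to 0.953 over left-out libraries. The cause of these sign changes was not tested. Counts of 1 or 2 called members in a list often changed when 1 library was left out, as for the risers among contractile genes (1, then 0 to 3), monocyte markers (2, then 0 to 2) and complement genes (1, then 0 or 1), and the fallers among capillary (2, then 1 to 3), mesothelial (2, then 1 or 2), dendritic cell (2, then 1 or 2), T cell (2, then 0 to 2) and interferon response genes (2, then 0 to 2).

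With the replicate number as a block, the replicate block fit called 2878 higher, 2824 lower, 1758 past 1 and 29 lists. Deviations of same-numbered libraries correlated across genes by 0.0887, −0.00467, 0.000325 and −0.0922, so the numbers do not pair the samples. Depth limits the genes with few counts, of which 1619 had under 5 in all.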

Other observations

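C2H2 zinc finger genes, a large family of DNA-binding factors, were more often higher than lower in KO_BLM. Of 450 tested, 137 rose and 41 fell, at a median log2 fold change of 0.226. They fill the KEGG herpes simplex virus 1 term, in which 111 of 391 tested genes were higher (adjusted p = 0.000207), 75 of the 111 being zinc finger genes, as were 205 of the 391. Proteasome genes shifted the other way, with 25 of 44 lower, 4 higher and a median log2 fold change of −0.262.

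The tests of blood, lymph node, dilution, mesenchymal share, injury and the second test of abundant genes were chosen after the results they bear on were seen; those of gene length, GC content, the planned test of abundant genes and the splits were written after the main results but before their own values were seen. Other splits of the 8 libraries mix the genotypes. Of 35 splits, only the real one gave as many genes higher (3057), lower (3061) and past an absolute log2 fold change of 1 (1783). By edgeR the highest of the other splits was 0 for each, with up to 1427 genes at an unadjusted p below 0.05 against 7536. These splits carry the genotype difference in their spread within groups, which holds their calls down. Chance alone would rank the real split first in 1 of 35 cases, so the gene counts argue against chance only to that limit. The real split also gave 177 terms and the others 0, but with 0 genes called no term could pass, so the terms are no separate evidence. Chance is not excluded for the number of lists called by camera's preset correlation, since 14 of 35 splits gave at least the real 23 and the highest other gave 30. That comparison is limited, as 12 of the 14 keep 3 libraries of each genotype together and so carry part of the genotype difference, but of the 18 splits that divide each genotype evenly 1 also gave 23.

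Ribosome genes were lower and zinc finger genes higher by small amounts across many members. After each library's trend over gene length was removed, the medians were −0.284 (95% bootstrap interval −0.309 to −0.247) and 0.212 (0.162 to 0.270), and after the trend over GC content −0.257 (−0.287 to −0.235) and 0.209 (0.158 to 0.247), against −0.240 and 0.226 before. These argue against either trend as the whole cause. RNA quality and library batch are not given and stay open, as does an effect of the genotype, which may act through changed cell makeup.

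Natural killer, T and B cell markers were higher in KO_BLM. Haemoglobin rose by 1.11 in mean log2 CPM, and more blood in the lungs would raise these lists no more if its cells rose alike. Natural killer markers rose by 1.6 more (exact permutation p = 0.0286), which under that assumption argues against blood as the whole source. T cell markers (−0.104, exact permutation p = 0.743) and B cell markers (0.597, exact permutation p = 0.257) cannot be told apart from haemoglobin at 4 against 4. The platelet gene Ppbp, also carried in blood, had a log2 fold change of 2.30, so haemoglobin may be no upper bound. Dilution by more mesenchyme in WT_BLM would raise all other cell types alike. The lymphoid lists, pooled, rose by 1.30 more than type 1 alveolar and capillary markers (exact permutation p = 0.0286), which rose by 0.209 and 0.538. Type 2 alveolar markers rose by 1.15, against 2.71 for natural killer, 1.71 for B cell and 1.01 for T cell markers. The pooled test therefore does not settle dilution for T cells, and the lymphoid lists were not tested apart. Carried-over lymph node would raise lymphatic markers, which were lower (−0.868, exact permutation p = 0.0286); this met the bound as first written, but their high baseline could hide a small piece of node, so a condition on it was added afterwards and the question stays open. A genotype effect on lymphocyte numbers is a hypothesis that bulk counts leave untested.

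Matrix genes were lower in KO_BLM, while resident fibroblast markers were higher (0.615, exact permutation p = 0.0286). This argues against a smaller share of resident fibroblasts in the pieces used. These markers do not measure myofibroblasts or scarred tissue, so a smaller share of those in the pieces stays open. Without the 20 most abundant genes, the planned test was undecided. The median of the 35 matrix genes left was −1.74, against −1.75 in the main fit. Its interval of −2.22 to −0.850 reached past the preset bound of −0.876, which is 0.5 times the main median. That interval reflects the spread among matrix genes and not the effect of the abundant ones. The 20 genes held 6.47% to 7.93% of counts in WT_BLM libraries and 8.20% to 9.23% in KO_BLM libraries. Shares this small cannot lower other genes as far as the matrix genes fell. They argue against counts taken by these 20 genes as the cause. A second test, added because the planned one was undecided, used library totals alone, which do not centre the genes; it replaced one on TMM-scaled values, whose centring had fixed the outcome. Counts taken by a few genes would lower all others alike. The genes outside the list had a median of 0.0893 (95% bootstrap interval 0.0817 to 0.0973) against −1.66 for the matrix genes. The bound of this test was 0.5 times −1.66. With the 20 most abundant genes at 9.23% of counts or less, the median outside the list could hardly have reached it. The outcome was thus nearly fixed in advance as well, and no conclusion is drawn from this second test. Less bleomycin injury in KO_BLM is a candidate explanation that stays open: p53 and damage genes were lower (−0.304, exact permutation p = 0.0286), but a changed response to equal injury would lower them too.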
